A study of Homo sapiens with 33 samples.

How the data were processed

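The samples came from 2 human cell lines that carried wild-type (WT) hnRNPA1 or hnRNPA1 with the D262V substitution in its C-terminal low complexity domain. SH-SY5Y is a neuroblastoma line that can be differentiated toward neurons. Flp-In T-REx 293 is a kidney-derived line in which a transgene is switched on by tetracycline. RNA-seq covered 7 groups of 3 libraries: undifferentiated WT and homozygous D262V SH-SY5Y cells, differentiated WT, homozygous and heterozygous D262V SH-SY5Y cells, and Flp-In cells with the WT or the D262V transgene. Per the labels' protocols, differentiation ran to day 18 with 10 µM retinoic acid and, in the last medium, 50 ng/mL BDNF, and the Flp-In cells had 1 µg/mL tetracycline for 72 hr. Infrared crosslinking and immunoprecipitation (irCLIP), which maps where a protein touches RNA, covered 4 groups of 3 samples. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Replicates of a group differed by more than counting noise, and none was counted as a copy of another.

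Per the labels' protocols, poly(A) RNA was used with a directional NEBNext Ultra library kit. The submitters' processing notes name STAR 2.5.3a, HTSeq, DESeq2 and Cufflinks, and the build hg38. The annotation and the strand setting of the counting are not given in the sources used here. The deposited gene counts are whole-number read counts per gene symbol, in 1 table each for undifferentiated SH-SY5Y, differentiated SH-SY5Y and Flp-In cells. The table holds 44786 gene rows. Of these, 26565 matched a symbol in the gene-name table and 26314 a RefSeq gene of assembly GRCh38.p14, of which 17989 are protein-coding. No column was left unmatched to a sample. Rows that name no gene were kept out of library sizes and tests. The row for reads that the counting placed in no gene feature held most of the uniquely aligned reads. Its share was 92.2% to 93.1% in differentiated SH-SY5Y cells, 94.4% to 94.6% in undifferentiated cells and 93.6% to 94.2% in Flp-In cells. These reads need not lie outside genes, since most genes had fewer counts than reads over a single junction of their own. Reads in genes came to 3.62 to 6.85 M per library in undifferentiated SH-SY5Y cells, 8.72 to 15.3 M in differentiated cells and 1.99 to 2.91 M in Flp-In cells.

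The authors' splicing tables, in the format of the JUM program, list per junction the read counts in each library, the junction's usage as a percent of its splice choice, and a likelihood-ratio p-value with its Benjamini-Hochberg adjusted p-value, all as deposited. Events are cassette exons, alternative 5' and 3' splice sites, mutually exclusive exons, retained introns and composite events that mix these. A junction listed by the authors was taken as changed when the authors' deposited table gave an adjusted p under 0.05, mean usage moved by at least 0.1 as a fraction, every library had at least 20 reads over the event, and the usage values of the groups did not overlap. By chance 10% of events with 3 against 3 libraries do not overlap. The tables list events that the authors had already selected, so shares of listed events describe that selection. The irCLIP files list clusters for the pooled replicates of a group, each with the authors' score, a whole number whose unit is not given in the sources used here. This score is the authors' own value per cluster and is used only within a list. Clusters were assigned to genes by coordinates and strand.

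Gene counts were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, its default filter on low counts, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Each of the 3 tables was fitted by itself with its groups sharing an estimate of spread. The fit over WT and homozygous libraries of both states gave the effect of differentiation in WT cells and the interaction of genotype and differentiation. In that fit the table and the differentiation state cannot be told apart. DESeq2 1.42.0 was an alternative. Gene lists fixed in advance were tested with camera in limma 3.58.1 at a preset correlation of 0.01, over lists with at least 5 tested members. The lists were ALS and FTD genes, the hnRNP family, SR proteins and core spliceosome, neural splicing regulators, stress granule components, nonsense-mediated decay and exon junction complex, synaptic genes, axon and cytoskeleton genes, voltage-gated channels, noradrenergic identity, mesenchymal markers, Schwann and glial markers, proliferation, retinoic acid response, activity-regulated genes, unfolded protein and integrated stress response, heat shock and chaperones, interferon response, p53 targets, cholesterol synthesis, hypoxia and glycolysis, mitochondrially encoded genes, and genes with known hnRNPA1-regulated splicing.

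The named genes were set by a rule: HNRNPA1, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those past the threshold with mean log2 CPM of at least 2 and groups that do not overlap (5 each way for the interaction, the differentiation effect and homozygous against heterozygous cells), and up to 4 members per list. For splicing the rule took the 2 largest changes per event class and changed events in ALS and FTD genes or genes with known hnRNPA1-regulated splicing. Lists, tests, thresholds, alternatives and this rule were chosen before the data were examined. Genes named by their junction reads, the direction of retained introns, microexons and the exon-level account of HNRNPA1 were chosen after their values were seen. A few genes that met the rule are not reported here.

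After the data were seen, junction reads of the splicing tables were summed per gene and tested with edgeR in the same way, with the totals of the count tables as library sizes. This measure covers genes with listed events only and sums their listed junctions, so a shift in usage can by itself change the sum. The measure was added because gene counts lay below the reads of single junctions of the same gene for most genes. Strand was known from the deposited files for 14503 genes, of which 1406 overlapped a gene on the other strand. Exons of at most 27 nt were called microexons. Log2 fold changes are D262V against WT with standard errors (SE), CPM values are gene counts scaled with TMM to the usual common total, and percent usage has its SD over 3 libraries. Where a group had no read, the fold is a lower bound against a floor of 3 counts per library. Intervals and floors cover counting error only.

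The scripts' statistics were tested on simulated data with 100 genes changed per fold size. edgeR recovered 22% of 2-fold and 55% of 4-fold changes in the undifferentiated comparison over 11313 genes, with 4.94% false calls. In the differentiated homozygous comparison over 16092 genes, the number in a fit of its 6 libraries alone, it recovered 79% and 99%. The reported results there come from the fit of all differentiated groups over 16833 genes, for which recovery was not tested. In Flp-In cells over 9148 genes it recovered 43% and 77%. Alternatives were DESeq2, RLE scaling, no filter, the replicate number as a block, each library left out, other thresholds for events, and other overlaps for clusters. The software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.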

Results

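RNA was sequenced from 21 samples in 7 groups of 3. SH-SY5Y neuroblastoma cells were sampled undifferentiated, with WT or homozygous D262V hnRNPA1, and differentiated for 18 days, with WT, homozygous or heterozygous D262V hnRNPA1. Flp-In T-REx 293 cells expressed a tetracycline-induced WT or D262V transgene. Total reads per library were 87.3 to 159 M in undifferentiated SH-SY5Y cells, 131 to 214 M in differentiated cells and 35.3 to 49.1 M in Flp-In cells. Reads counted in genes were 4.14% to 4.35%, 6.64% to 7.45% and 5.65% to 6.20% of these totals. Undifferentiated totals held 18.1% to 19.0% of reads not uniquely aligned, recorded as 0% in the other cells, so these shares are not like for like. irCLIP binding clusters of hnRNPA1 were listed for WT and D262V cells of both lines, with 3 samples pooled per list, and the labels give neither the zygosity nor the differentiation state of those SH-SY5Y cells. Folds are D262V over WT with n = 3 libraries per group unless another n is stated, and ± gives the SD over those libraries.

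The gene counts lay below the junction reads of the same genes. In WT Flp-In libraries, 1744 of 1874 genes (93.1%) had fewer gene counts than reads over their own most-read junction, and in the WT SH-SY5Y libraries of the 3 SH-SY5Y comparisons 87.7% to 88.4% did. The median gene count was 6.31% to 9.44% of that single junction. Antisense-named genes had more reads than their sense partners in 305 of 577 pairs (52.9%) in differentiated SH-SY5Y cells, 252 of 399 (63.2%) in undifferentiated cells and 211 of 306 (69.0%) in Flp-In cells. In differentiated WT SH-SY5Y cells DBH-AS1 had a mean of 94974 reads and DBH, the noradrenaline-making enzyme, 1436. In Flp-In WT cells VIM-AS1 had 8039 reads and vimentin (VIM) 94.7. Log2 fold changes by gene counts and by junction reads correlated across genes at r = 0.20 in the undifferentiated homozygous comparison, 0.47 in the differentiated homozygous comparison, 0.41 in the heterozygous comparison and 0.30 in Flp-In cells. Genes are not independent replicates. By junction reads 538 of 4806 genes changed in undifferentiated homozygous, 1758 of 5382 in differentiated homozygous, 1618 of 6544 in heterozygous and 539 of 3301 in Flp-In cells. Genes called by both measures numbered 18, 156, 358 and 37, of which 15, 144, 304 and 32 moved the same way in both. Results by gene counts are therefore given together with junction reads where a gene had them, and each comparison of D262V with WT opens with genes that passed by both measures.

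The splicing of HNRNPA1 itself was the first question, since the D262V codon lies in this gene. In SH-SY5Y cells with D262V, reads that left the optional exon at 12: 54283078-54283233 (156 nt, plus strand, hg38) mostly passed over the next exon at 12: 54283811-54283966 (156 nt) and joined the following one. In undifferentiated WT cells 0% of the reads leaving the optional exon did so, from 827, 900 and 284 reads, which allow up to 0.363%, 0.333% and 1.06%. In undifferentiated homozygous cells the share was 90.03% ± 2.76. In differentiated cells it was 1.48% ± 0.11 in WT and 85.6% ± 0.51 in homozygous cells. Heterozygous cells had 85.7% ± 0.51 against 1.52% ± 0.11 in WT from the heterozygous table. The optional exon itself was used more: its share rose from 7.54% ± 2.24 to 48.8% ± 2.13 in undifferentiated homozygous cells, from 9.13% ± 0.80 to 55.1% ± 1.14 in differentiated homozygous cells and from 9.05% ± 0.76 to 52.1% ± 2.59 in heterozygous cells. A further share was taken over reads that joined the optional exon or the next exon to the exon after it. Of these, 24.2% ± 1.06 had passed over the next exon in undifferentiated homozygous cells. The share was 46.7% ± 0.26 in differentiated homozygous and 42.9% ± 1.85 in heterozygous cells. Reads over other junctions into that exon, if any, were left out. Undifferentiated and differentiated cells were not compared on this share. In Flp-In cells, where D262V came from a transgene, the optional exon share was 3.19% ± 0.66 in WT and 1.85% ± 0.12 in D262V cells, and the junction past the next exon was not listed. Whether the exon passed over holds the D262V codon was not determined here. The groups did not overlap in any of these measures, and the 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. HNRNPA1 junction reads fell in undifferentiated homozygous cells (log2 fold change -0.38, SE 0.11, adjusted p = 0.024). The shift in junction use can by itself change this sum. By junction reads the change was -0.19 (adjusted p = 0.053) in differentiated homozygous, -0.07 (adjusted p = 0.66) in heterozygous and -0.08 (adjusted p = 0.57) in Flp-In cells. By gene counts HNRNPA1 passed in none of these 4 comparisons: -0.28 (adjusted p = 0.75), 0.31 (adjusted p = 0.38), 0.33 (adjusted p = 0.24) and 0.08 (adjusted p = 0.83).

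**Figure D1:**
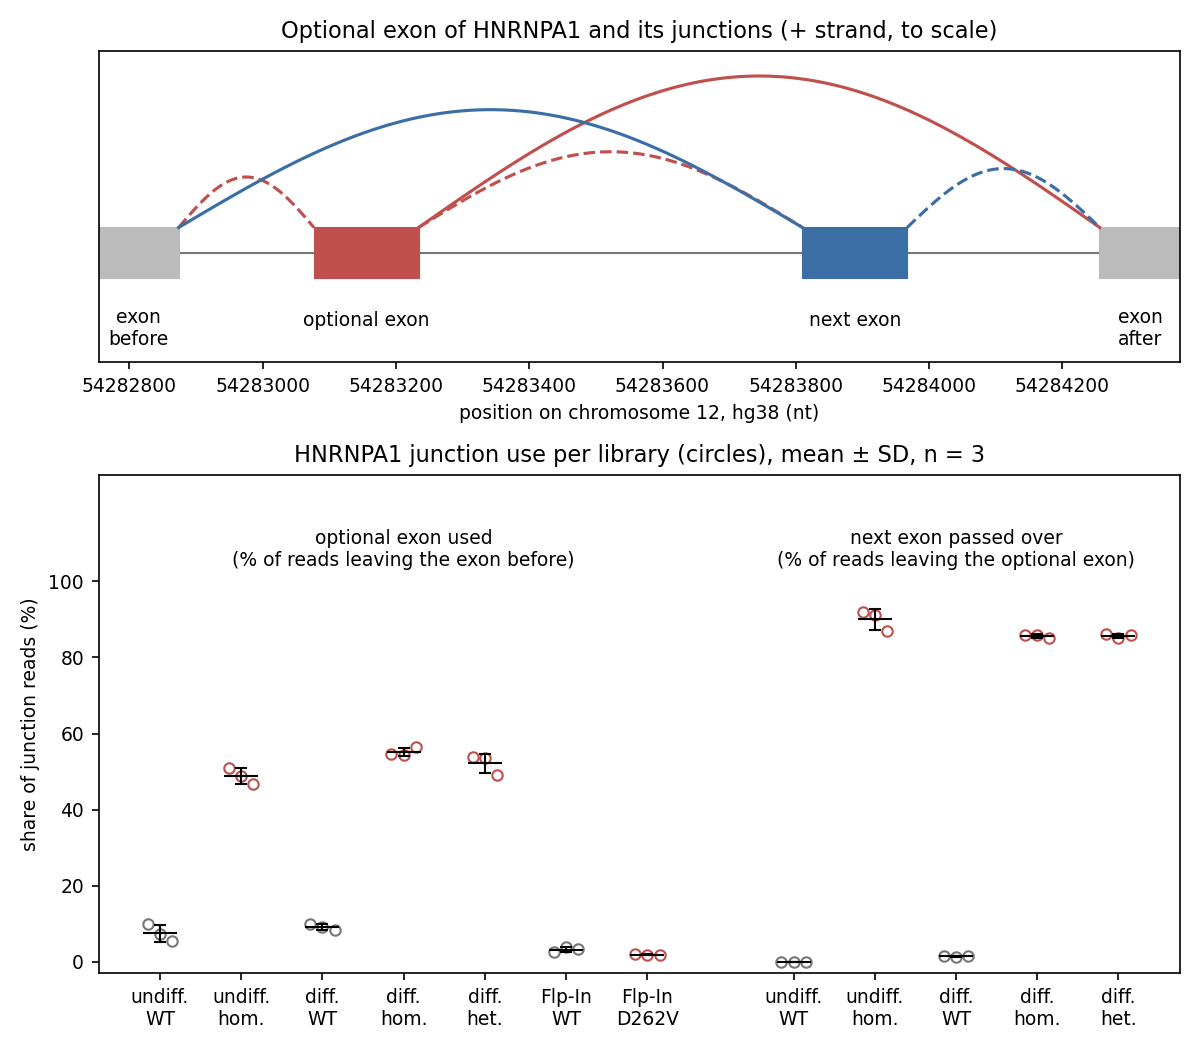
Map of the HNRNPA1 exons on chromosome 12 (position in nt, hg38) with the junctions of the optional exon, and, per library, the percent of reads that leave the optional exon and pass over the next exon and the percent of use of the optional exon. Each point is 1 library and each line a group mean. The homozygous libraries average 90.03% undifferentiated and 85.6% differentiated, and the WT libraries 0% and 1.48%.

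The comparison of undifferentiated homozygous and WT cells asked what D262V changes before neuronal differentiation. IGF2, a growth factor, had 432 to 799 CPM in the WT libraries and fell to 82.2 ± 7.7 CPM (log2 fold change -2.79, SE 0.22, adjusted p = 8.8e-05), and by junction reads by 2.17. The noradrenaline transporter gene SLC6A2 (-3.19, SE 0.78) and the vesicle granin gene CHGB (-1.50, SE 0.27) fell by both measures. RET, a receptor tyrosine kinase of neural crest cells, rose by both (1.78, SE 0.42, adjusted p = 0.043; junction reads 1.62, SE 0.14). The collagen gene COL3A1 rose from 0.519 ± 0.34 to 33.7 ± 5.8 CPM (6.03, SE 0.56) and COL5A1 from 0.715 ± 1.2 to 22.1 ± 2.3 CPM (4.81, SE 0.96), neither with listed junctions. In all, 415 of 11313 genes changed, 176 up and 239 down, and 203 up and 184 down without WT library 1. ORAI3 and ALDH1L2 had no read in any WT library and were at least 14.4-fold and 13.2-fold higher in homozygous cells. RALGAPA1 fell by gene counts from 60.6 ± 4.4 to 4.61 ± 2.6 CPM, yet its junction reads changed by 0.15 (adjusted p = 0.81). VIM rose by gene counts (2.85, SE 0.48), where VIM-AS1 overlaps it on the other strand.

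Of the fixed lists in undifferentiated cells, cholesterol synthesis (13 genes, adjusted p = 0.0091), heat shock and chaperones (9 genes, adjusted p = 0.0072) and proliferation (19 genes, adjusted p = 0.048, and 0.052 with RLE scaling) were lower in homozygous cells. With an estimated correlation their adjusted p was 0.484, 0.46 and 0.473. By gene counts no cholesterol or proliferation gene passed, and 1 heat shock gene fell, DNAJB1 (-1.18, SE 0.21), which encodes a chaperone and whose counts overlap TECR. Adjusted over the list alone, 2 cholesterol genes and 2 heat shock genes fell. Junction reads showed the same direction for these lists, with more members: 14 of 16 proliferation genes fell, among them RRM2 (-1.85, SE 0.19), PCNA (-1.15, SE 0.14) and MCM3 (-1.28, SE 0.16), and the list test gave adjusted p = 1.4e-09 (adjusted p = 0.036 with an estimated correlation). All 5 measured heat shock genes fell, such as HSP90AA1 (-1.35, SE 0.14) and HSPB1 (-0.76, SE 0.13), with list adjusted p = 1.7e-04 and 0.081 with an estimated correlation. In cholesterol synthesis 3 of 6 fell, with FDPS at -1.02 (SE 0.12; list adjusted p = 2.9e-04, and 0.081 with an estimated correlation). The hnRNP family also fell by junction reads, 11 of 16 genes with none up, including HNRNPM (-0.89, SE 0.13) and HNRNPDL (-0.84, SE 0.13), with list adjusted p = 2.4e-05 and 0.186 with an estimated correlation. By gene counts none of 23 hnRNP genes passed (list adjusted p = 0.749). By gene counts none of 24 ALS and FTD genes passed (list adjusted p = 0.973), and adjusted over the list alone 1 rose and 2 fell. By junction reads HNRNPA2B1 (-0.63, SE 0.13) and HNRNPA1 were among those that fell. Both also changed in splicing, and a shift in usage can by itself lower the junction sum of a gene. The gene count of this comparison moved with the settings: DESeq2 called 817, no filter 816, and leaving out 1 library gave 98 (without homozygous library 3) to 428. Of the 23 genes that the naming rule took here, 19 lost their call under at least 1 alternative.

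The comparison of differentiated homozygous and WT cells asked the same after 18 days of differentiation. Peripherin (PRPH), a neuronal intermediate filament with rare ALS variants, rose from 1.75 ± 0.81 to 23.1 ± 3.8 CPM (3.78, SE 0.30, adjusted p = 3.9e-10), and by junction reads by 3.28. The cell adhesion gene TENM1 rose from 1.18 ± 0.053 to 21.9 ± 3.3 CPM (4.19, SE 0.30; junction reads 3.35), and IGFBP5 (2.35, SE 0.19) and FAM78B (2.70, SE 0.17) rose by both measures. Neurofilament light chain (NEFL) rose from 104 ± 3.2 to 180 ± 22 CPM (0.79, SE 0.13; junction reads 0.95) and the growth cone gene GAP43 from 274 ± 26 to 447 ± 65 CPM (0.70, SE 0.13; junction reads 0.63). CRABP2, which carries retinoic acid to the nucleus, fell from 211 ± 29 to 76.1 ± 5.6 CPM (-1.48, SE 0.14; junction reads -2.33), and CYP26A1, which degrades retinoic acid, fell from 45.3 ± 1.9 to 20.9 ± 1.8 CPM (-1.12, SE 0.16; junction reads -0.93). SLC6A2 fell (-1.52, SE 0.24) while CHGB rose (0.86, SE 0.15), both also by junction reads. In all, 1024 of 16833 genes changed, 525 up and 499 down. BANP rose and MRPL19 fell by gene counts (2.52, SE 0.32, and -3.70, SE 0.39), whereas their junction reads changed by -0.20 (adjusted p = 0.15) and 0.06 (adjusted p = 0.79).

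Axon and cytoskeleton genes were higher in differentiated homozygous cells: of 30, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with list adjusted p = 0.0054 and adjusted p = 0.788 with an estimated correlation. By junction reads 13 of 26 rose and 2 fell (adjusted p = 0.0037, and 0.246 with an estimated correlation). The members that rose by both included PRPH, NEFL, NEFM (0.57; junction reads 0.79) and GAP43, and DPYSL3, a collapsin response mediator, fell (-0.66, SE 0.13; junction reads -0.69). Activity-regulated genes were lower, with 4 of 13 down (EGR1 -1.81, EGR3 -2.69, DUSP6 -1.11 and IER2 -1.08) and DUSP4 up (list adjusted p = 0.0079, and 0.638 with an estimated correlation; the same members adjusted over the list alone). Of 13 mitochondrially encoded genes, MT-ND2 (0.57, SE 0.11) and MT-CYB (0.36, SE 0.11) rose, with 5 up adjusted over the list alone and list adjusted p = 0.0054 (0.788 with an estimated correlation). Only gene counts are reported for these genes, here and in the other comparisons, and the strand that was counted is not known. Among 34 ALS and FTD genes PRPH rose and none fell (list adjusted p = 0.326; 1 up adjusted over the list alone). No hnRNP gene of 28 passed by gene counts (adjusted p = 0.83). Of 18 proliferation genes MKI67 (1.47, SE 0.42) and TYMS rose (list adjusted p = 0.164), and by junction reads 6 of 7 rose (adjusted p = 0.011, and 0.267 with an estimated correlation). Retinoic acid response genes fell by junction reads in 6 of 10 cases (adjusted p = 0.026, and 0.430 with an estimated correlation), and by gene counts 2 of 13 fell and MEIS1 rose (adjusted p = 0.439). The p53 target GDF15 fell by both measures (-1.53, SE 0.35; junction reads -2.64), but TP53I3 rose by gene counts (0.80) and fell by junction reads (-0.30). The number of genes changed was 575 without WT library 1, 609 without WT library 2, and 650 to 675 without any 1 homozygous library, and a fit of these 6 libraries alone called 1832.

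The comparison of differentiated heterozygous and WT cells asked what the mutation does in the heterozygous state, in which dominant variants occur. The GTPase-activating protein gene ARHGAP36 fell from 57.1 ± 3.8 to 3.06 ± 0.58 CPM (-4.22, SE 0.21, adjusted p = 1.4e-14; junction reads -3.90). The neuropeptide genes GAL (-3.02, SE 0.20; junction reads -3.05) and NPY (-2.37, SE 0.24; junction reads -2.29) fell, as did SLC6A2 (-3.16, SE 0.27; junction reads -2.87). PRPH rose from 1.75 ± 0.81 to 20.1 ± 4.8 CPM (3.58, SE 0.30; junction reads 3.55). FABP7, a brain fatty-acid-binding protein, had 14.8 ± 2.7 CPM with no read in any WT library, at least 56.0-fold higher. HMGCS1, which makes the precursor of mevalonate, rose from 30.1 ± 0.53 to 85.6 ± 16 CPM (1.51, SE 0.16; junction reads 1.62). In all, 2767 of 16833 genes changed, 1342 up and 1425 down. NMD3 fell by gene counts (-3.56, SE 0.23), while its junction reads changed by -0.18 (adjusted p = 0.42).

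Cholesterol synthesis rose in heterozygous cells: of 18 genes 11 rose and 1 fell, the same counts adjusted over the list alone (list adjusted p = 1.5e-06, and 0.284 with an estimated correlation). DHCR7 (1.26, SE 0.16) and MSMO1 (1.59, SE 0.24), enzymes of the later steps, rose by both measures, and by junction reads 15 of 16 members rose with none down (adjusted p = 3.1e-10, and 0.035 with an estimated correlation). Mesenchymal or substrate-adherent cell markers were higher, with 8 of 16 up and none down, also adjusted over the list alone (list adjusted p = 9.2e-04, and 0.284 with an estimated correlation). They included the matrix genes SPARC (1.77, SE 0.30), COL3A1 (1.49, SE 0.33) and FN1 (0.90, SE 0.20; junction reads 2.46). Among neuronal genes DPYSL3 (-1.34, SE 0.13), DCX (-1.31, SE 0.22) and NCAM1 (-0.60, SE 0.13) fell by both measures, and of 30 axon and cytoskeleton genes 6 fell and 1 rose (list adjusted p = 0.552; adjusted over the list alone 7 down, 1 up). CACNA2D1, a calcium channel subunit, fell (-1.72, SE 0.21; junction reads -1.60). SRRM4, a neural splicing regulator known for its role in microexon inclusion, fell from 7.42 ± 0.99 to 3.20 ± 0.63 CPM (-1.21, SE 0.31, adjusted p = 0.0065; junction reads -0.73, adjusted p = 0.030), and ELAVL4 fell by both (-0.65, SE 0.16; junction reads -0.40). These were the 2 of 17 neural splicing regulators that changed by gene counts (list adjusted p = 0.0841). Among 34 ALS and FTD genes PRPH rose and PFN1 (-0.63) and SQSTM1 (-0.37) fell by gene counts, with 1 up and 1 down adjusted over the list alone (list adjusted p = 0.81). HNRNPH2 (-0.54, SE 0.18) was the 1 hnRNP gene of 28 to pass (list adjusted p = 0.6), and none did adjusted over the list alone. Of 27 SR protein and core spliceosome genes 3 fell, SRSF1 (-1.04, SE 0.18; junction reads -0.36), U2AF2 and SNRPA, and SRSF9 rose (list adjusted p = 0.552).

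**Figure D2:**
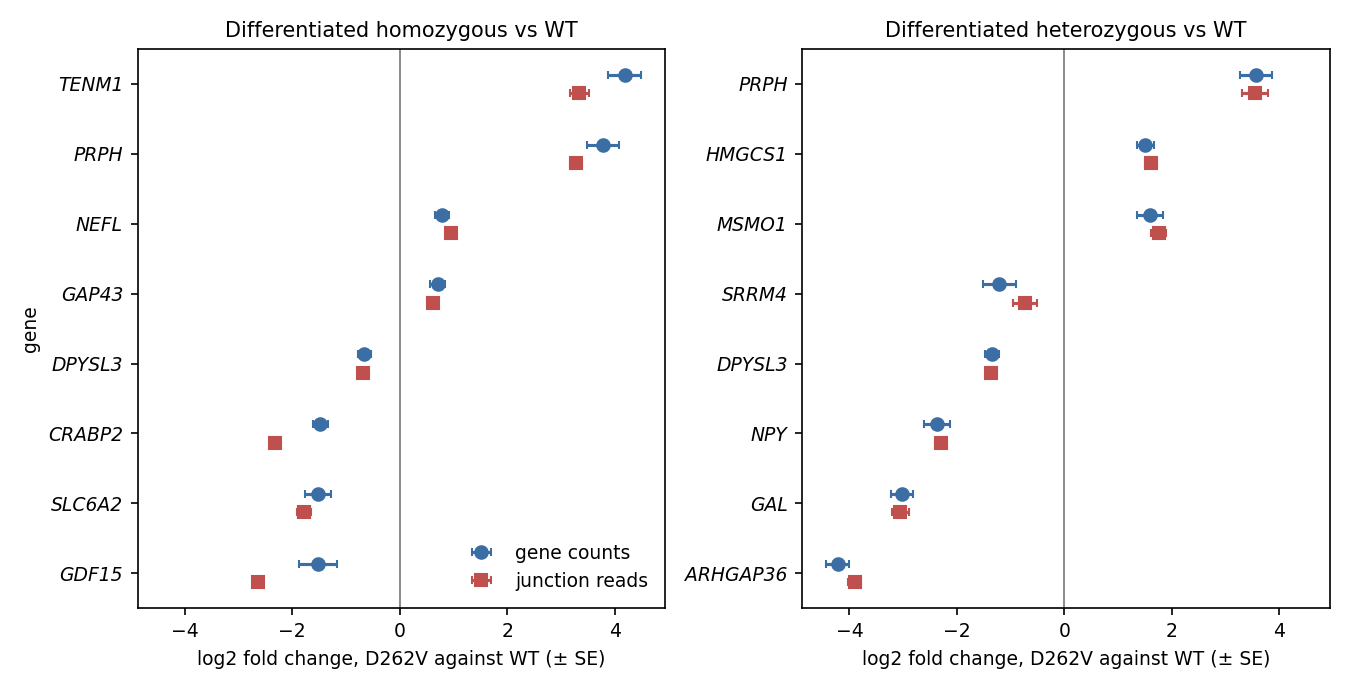
Log2 fold change of named genes in differentiated homozygous and heterozygous cells against WT (3 libraries per group) by gene counts and by junction reads; points are estimates and bars are ± 1 SE. PRPH stood at 3.78 by counts and 3.28 by junction reads in homozygous cells, and at 3.58 and 3.55 in heterozygous cells.

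Homozygous and heterozygous differentiated cells were compared with each other by gene counts, the only measure tested between them. Clones were not given separate labels, so differences between these genotypes need not follow from gene dose. TENM1 was higher in homozygous cells (21.9 ± 3.3 against 1.36 ± 0.43 CPM; 3.99, SE 0.31, adjusted p = 2.1e-10), and so was NPY (21.5 ± 2.2 against 4.03 ± 0.97 CPM; 2.41, SE 0.24). FABP7 had no read in any homozygous library and was at least 53.7-fold higher in heterozygous cells. SRRM4 was higher in homozygous cells (0.98, SE 0.31, adjusted p = 0.029), and HNRNPA1 was not seen to differ (-0.02, SE 0.18, adjusted p = 0.97). In all, 2674 genes differed, 1440 higher and 1234 lower in homozygous cells, where RLE scaling gave 1295 and 1351, and 1772 did without homozygous library 1. Axon and cytoskeleton genes were higher in homozygous cells (14 of 30 up, none down, 16 up adjusted over the list alone; list adjusted p = 2.0e-05), with DCX, MAP2 and NEFM among them. Cholesterol synthesis (10 of 18 down, none up; 12 down and 1 up adjusted over the list alone; list adjusted p = 2.7e-06) and mesenchymal markers (4 of 16 down, 5 adjusted over the list alone; list adjusted p = 0.017) were lower. With an estimated correlation the adjusted p of all 3 lists was 0.302.

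Both genotypes were compared with the same 3 WT libraries. They shared 518 genes changed in the same direction, 247 up and 271 down, where independent calls would give 41.9 and 42.2, and 50 genes went opposite ways. Log2 fold changes correlated across genes at 0.504, and data simulated with shared controls and no other common effect gave 0.495. The covariance was 0.263, against 0.0801 simulated. The WT libraries cannot be parted into groups of at least 2, so part of the excess may come from the shared controls. SLC6A2, CRABP2 and GAL fell and PRPH and PMP22, a myelin protein gene, rose in both.

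The effect of differentiation in WT cells was large by gene counts, the only measure tested for it. Here the change in state cannot be told apart from the change of table. CYP26B1, which degrades retinoic acid, had no read in undifferentiated WT cells and was at least 429-fold higher after differentiation. RET rose from 5.96 ± 0.72 to 343 ± 16 CPM (5.64, SE 0.15, adjusted p = 4.1e-13), STMN2, a neuronal microtubule regulator, from 34.0 ± 3.9 to 400 ± 11 CPM (3.35, SE 0.17) and CRABP2 by 5.05. DLK1, a marker of immature cells, fell from 197 ± 30 to 0.201 ± 0.20 CPM, and the cyclin gene CCNA2 from 193 ± 13 to 26.4 ± 1.5 CPM (-3.08, SE 0.16). In all, 7230 genes changed, 4459 up and 2771 down. Retinoic acid response genes (10 of 13 up, none down; list adjusted p = 3.4e-05, and 0.0144 with an estimated correlation) and axon and cytoskeleton genes (20 of 29 up, 1 down; 20 and 2 adjusted over the list alone; adjusted p = 0.0061, and 0.169 with an estimated correlation) rose. Proliferation genes fell, with 14 of 22 down and 1 up (list adjusted p = 6.0e-06, and 0.0129 with an estimated correlation). All 13 mitochondrially encoded genes fell (list adjusted p = 3.2e-13, and 0.169 with an estimated correlation).

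The interaction asked whether the homozygous effect differed between the states, with 755 of 16793 genes past the threshold, 354 positive and 401 negative, a balance that depended on scaling: RLE scaling gave 435 and 351. BMPR1B, a bone morphogenetic protein receptor (5.53, SE 1.2), CXADR (5.48, SE 0.69) and BANP (5.27, SE 0.62) had more positive D262V effects by gene counts after differentiation, and CHGB did too (2.36). BANP junction reads changed by -1.05 (adjusted p = 0.31) before and -0.20 (adjusted p = 0.15) after differentiation, and the interaction was not tested by junction reads. COL3A1 (-5.02), VIM (-2.70) and CRABP2 (-2.16) had more negative ones. The 6 lists that differed between the states were up for mitochondrially encoded genes (5 of 13, 7 adjusted over the list alone; adjusted p = 6.7e-04, and 0.366 with an estimated correlation), cholesterol synthesis (1 of 18, 4 over the list alone; 0.0034 and 0.218), proliferation (1 of 22, 1 over the list alone; 0.0034 and 0.0933), axon and cytoskeleton genes (3 of 29, 3 over the list alone; 0.011 and 0.208) and heat shock genes (1 of 10, 4 over the list alone; 0.025 and 0.169), and down for retinoic acid response (2 of 13, 3 over the list alone; 0.013 and 0.152). The heat shock list had a median of 0.51 and a mean of -0.07. The number of genes ranged from 359 to 1189 when 1 library was left out, and DESeq2 called 1672.

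In Flp-In cells the comparison of transgenes asked whether D262V acts in another cell type. Glycerol kinase (GK) fell from 22.6 ± 6.0 to 1.37 ± 0.45 CPM (-4.03, SE 0.49, adjusted p = 1.4e-05; junction reads -3.66), and the exosome nuclease gene DIS3 rose by both measures (0.83; junction reads 0.94). The homeobox gene HOXC8 rose from 2.87 ± 0.63 to 22.9 ± 4.9 CPM (2.98, SE 0.42). In all, 534 of 9148 genes changed, 252 up and 282 down, and with no filter 263 up and 241 down. LCP1 had no read in WT cells and was at least 8.39-fold higher. HOXB6 fell by gene counts (-2.83, SE 0.28), yet its junction reads changed by -0.01 (adjusted p = 0.97). By gene counts alone, mitochondrially encoded genes fell, 5 of 13 with none up and 10 adjusted over the list alone. Among them were MT-ND6 (-0.66, SE 0.13) and MT-ATP6 (-0.65, SE 0.14), with list adjusted p = 0.0014 and 0.893 with an estimated correlation. With counting on the opposite strand, such rows would not hold the genes' own RNA. HNRNPL (1.11, SE 0.27) and HNRNPUL1 (from 23.1 ± 2.0 to 52.2 ± 31 CPM) rose among 26 hnRNP genes by gene counts (list adjusted p = 0.444), and their junction reads changed by -0.08 (adjusted p = 0.76) and 0.15 (adjusted p = 0.21). The translation factor gene EIF4G1 rose by both (1.68, SE 0.36; junction reads 0.38), with 65.6 ± 51 CPM over the D262V libraries. No ALS or FTD gene of 24 passed (list adjusted p = 0.272). The count of genes was 209 without WT library 3, 265 without WT library 2, 277 without WT library 1 and 267 without D262V library 3. Of the 26 genes that the naming rule took here, 21 lost their call under at least 1 alternative, 13 of them with DESeq2.

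Splicing was compared to ask which transcripts of ALS-linked and other genes change. In undifferentiated homozygous cells 203 of 4660 listed events changed, in 196 genes: 67 cassette exons, 54 alternative 5' and 54 alternative 3' splice sites, 27 retained introns and 1 pair of mutually exclusive exons, with 145 composite events besides. HNRNPA2B1, an ALS-linked relative of HNRNPA1, kept the intron at 7: 26192240-26192436 with a usage of 53.1% ± 2.8 within its splice choice against 30.4% ± 2.2 in WT. The sodium channel gene SCN3A used one junction of its exclusive exons (2: 165162828-165163800) in 64.7% ± 6.7 against 14.2% ± 2.4. The chromatin gene SMARCA2 used the 5' splice site of the junction at 9: 2123937-2161684 in 49.4% ± 6.9 against 94.6% ± 4.8. Of the changed cassette exons 29 of 67 (43.3%) were skipped more (exact binomial adjusted p = 0.56), and of the changed introns 22 of 27 were retained more (adjusted p = 0.0061). The direction of introns no longer passed with a change of at least 0.2 (12 of 15, adjusted p = 0.14), the authors' adjusted p under 0.01 (7 of 9, adjusted p = 0.36) or at least 50 reads (16 of 21, adjusted p = 0.11). These tests treat events as independent.

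In differentiated homozygous cells 174 of 5123 listed events changed, in 145 genes, with 82 alternative 5' splice sites, 49 retained introns, 26 cassette exons and 17 alternative 3' splice sites, and 125 composite events. HNRNPA1 retained the stretch at 12: 54284091-54284364, downstream of the optional exon, in 90.1% ± 1.8 against 29.8% ± 10.1. APP, the amyloid precursor gene, used the junction at 21: 25997416-26021838 in 19.4% ± 1.2 against 34.2% ± 0.80. INPP5F, an inositol phosphatase gene, used the junction at 10: 119819539-119820844 in 0.907% ± 0.59 against 85.3% ± 2.1. RGS8, a regulator of G-protein signalling, used the 5' splice site at 1: 182672932-182674722 in 14.6% ± 3.8 against 87.9% ± 8.0. The tropomyosin gene TPM1 used the 3' splice site at 15: 63062645-63071088 in 63.1% ± 4.1 against 30.7% ± 8.9. Cassette exons went both ways, 13 of 26 skipped more (adjusted p = 1), and 31 of 49 introns were retained more (adjusted p = 0.0998).

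In heterozygous cells 586 of 6796 listed events changed, in 500 genes, with 184 cassette exons, 179 retained introns, 159 alternative 5' and 63 alternative 3' splice sites and 1 pair of exclusive exons, besides composite events. DCTN1, the dynactin gene with ALS-linked variants, included its 15 nt exon at 2: 74363613-74363627 in 74.3% ± 2.6 against 91.3% ± 0.19. EWSR1, another ALS-linked RNA-binding protein gene, retained an intron (22: 29299046-29299319) in 75.2% ± 8.3 against 52.7% ± 4.0. APP used the junction at 21: 25982477-26000013 in 50.2% ± 0.82 against 75.2% ± 0.57. The 12 nt exon of LRRC16A at 6: 25507478-25507489 was included in 31.5% ± 7.1 against 95.3% ± 8.1, and the 20 nt exon of the apoptosis gene BAK1 at 6: 33574505-33574524 in 28.7% ± 9.5 against 87.3% ± 2.2. TPM1 shifted as in homozygous cells, to 72.5% ± 2.5 from 30.6% ± 8.5. Of the changed cassette exons 109 of 184 (59.2%) were skipped more (adjusted p = 0.059), and 78 of 179 introns were retained less (adjusted p = 0.0998).

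Exon length set the skipped exons of heterozygous cells apart. Of 53 changed microexons of at most 27 nt, 51 were skipped more, against 58 of 131 longer exons (Fisher's exact test, adjusted p = 1.2e-11). Among all listed cassette exons 104 of 118 microexons (88.1%) and 506 of 1424 longer exons (35.5%) were skipped more. Examples were the 23 nt exon of the kinesin gene KIF1C, included in 32.7% ± 3.4 against 83.0% ± 1.0, and the 9 nt exon of the dystrobrevin gene DTNA, in 64.0% ± 9.3 against 96.6% ± 1.7. In homozygous cells 48 of 56 listed microexons (85.7%) and 459 of 950 longer exons (48.3%) were skipped more, which is no separate support, since simulated shared WT libraries alone gave the same direction at 96.3% of cassette exons. Of the 45 microexons listed in both comparisons, 43 moved further in heterozygous cells (median -15.1 against -6.83 points). Only 3 of these passed in homozygous cells. In undifferentiated homozygous cells 20 of 41 listed microexons and 613 of 1348 longer exons were skipped more (adjusted p = 0.75). Of the changed ones there 4 of 4 microexons and 25 of 63 longer exons were (adjusted p = 0.062), and so were 8 of the 9 microexons changed in heterozygous cells and listed there (median -9.35 points), with other WT libraries. In Flp-In cells 9 of 24 listed microexons were skipped more, against 679 of 1063 longer exons (adjusted p = 0.013). Changed cassette exons of heterozygous cells had a length divisible by 3 in 66.8% of 184 cases, against 48.5% of the other listed ones (Fisher's exact test, adjusted p = 1.2e-05). The 184 include the 53 changed microexons, most of which had such a length, and longer exons were not tested alone.

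**Figure D3:**
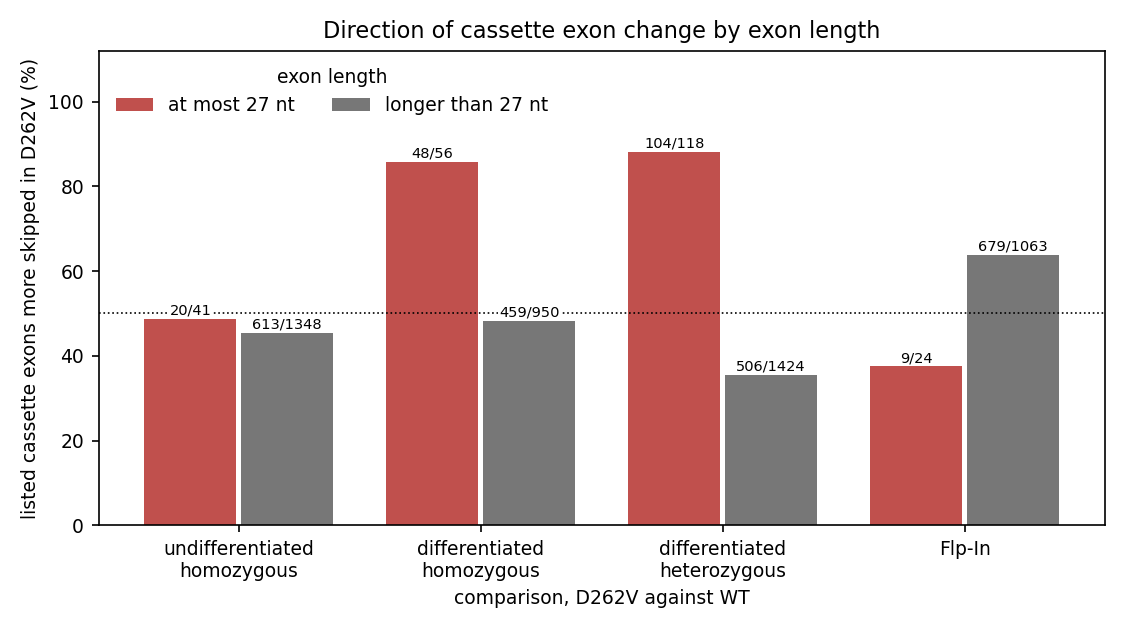
Percent of listed cassette exons skipped more in D262V than in WT cells, for exons of at most 27 nt and for longer ones, in each comparison of 3 against 3 libraries. Bars are shares with the number of exons printed, and in heterozygous cells 88.1% of the short and 35.5% of the longer exons were skipped more.

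In Flp-In cells 76 of 2951 listed events changed, in 74 genes, with 38 cassette exons, 18 alternative 5' and 12 alternative 3' splice sites and 8 retained introns, and 46 composite events. ANXA11, an ALS-linked annexin gene, used the junction at 10: 80176155-80180939 in 12.9% ± 4.5 against 1.40% ± 1.4. USPL1, a SUMO protease gene, included its 167 nt exon at 13: 30621072-30621238 in 33.2% ± 4.9 against 70.8% ± 6.0, and SH3BGR used the 5' splice site of the junction at 21: 39452141-39462373 in 80.4% ± 6.0 against 31.0% ± 4.6. Of the cassette exons 22 of 38 were skipped more and of the introns 7 of 8 were retained more.

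The comparisons shared few of their events outside the differentiated pair. Of 1127 junctions listed in both differentiated comparisons, 1077 (95.6%) moved the same way, where simulated shared controls alone gave 96.5%, and the covariance was 0.0218 against 0.00120 simulated. All 53 events changed in both moved the same way. Homozygous and heterozygous usage did not overlap in 108 of 195 events changed in heterozygous cells (55.4%, with 10% by chance), with median changes of 13.3 points in homozygous and 22.1 points in heterozygous cells. They did not overlap in 32 of 84 events changed in homozygous cells (38.1%, median changes 21.6 and 24.0 points) and in 240 of all 1127 listed in both (21.3%). Undifferentiated and differentiated homozygous cells moved the same way at 60.1% of 168 junctions (exact binomial adjusted p = 0.027). With fewer junctions the share was no lower but no longer passed. It was 66.7% of 30 junctions changed by at least 0.1 in both (adjusted p = 0.25) and 63.6% of 77 cassette exons (adjusted p = 0.055). Heterozygous SH-SY5Y and Flp-In cells moved the same way at only 48 of 168 (28.6%, exact binomial adjusted p = 1.3e-07), and opposite ways at the rest. Among cassette exons the share was 28 of 105 (26.7%), where the margins alone give 40.8% (Fisher's exact p = 6.9e-04).

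Genes with changed splicing were compared with genes changed in counts. In heterozygous cells 87 of 454 such genes (19.2%) also changed in counts, with a median of 18.1% in 10000 random gene lists of like expression. The shares were 2.33% against 3.10% in undifferentiated homozygous cells, 8.87% against 6.45% in differentiated homozygous cells and 14.0% against 4.65% in Flp-In cells, where 6 of 43 genes lay at percentile 97.5 of the random lists. With DESeq2 4 of the 43 did (9.30%), at percentile 89.8. By junction reads the genes with changed splicing were called in 154 of 499 cases (30.9%) in heterozygous cells against 24.2% of other genes, 38.6% against 32.5% in differentiated homozygous, 10.7% against 11.2% in undifferentiated homozygous and 23.0% against 16.2% in Flp-In cells. Both sides of this comparison use the same junction reads, so a shift in usage can by itself change the sum for a gene. These shares were not matched for expression and not tested.

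The irCLIP lists held 583264 clusters in WT and 539011 in D262V SH-SY5Y cells, and 519183 and 483849 in Flp-In cells. Of the WT clusters 84.8% in SH-SY5Y and 83.0% in Flp-In cells overlapped a D262V cluster, and 89.2% and 87.5% of the D262V clusters overlapped a WT cluster. Unshared clusters had low scores, with medians of 25 against 65 for shared ones in WT SH-SY5Y cells. The genes with the most clusters were long ones, LINGO2 with 1417 and CCSER1 with 1412 in WT SH-SY5Y cells and FHIT with 1397 in WT Flp-In cells. HNRNPA1 had 11 clusters in WT and 10 in D262V SH-SY5Y cells, and 9 and 8 in Flp-In cells. In D262V SH-SY5Y cells 2 clusters overlapped its optional exon, the higher with a score of 107, and 0 in WT cells. The intron after it also had 2 clusters in D262V SH-SY5Y cells with a highest score of 107, which may be the same cluster. D262V SH-SY5Y cells also used this exon more, so the counts do not part binding from the amount of RNA. APP had 282 and 259 clusters, HNRNPA2B1 30 and 34, and DCTN1 24 and 22 in WT and D262V SH-SY5Y cells. In undifferentiated homozygous cells, exons included more had a WT cluster within the span of the event in 26 of 38 cases (68.4%) and exons skipped more in 18 of 29 (62.1%; Fisher's exact p = 0.61), with 67.5% among other listed exons. In Flp-In cells the counts were 12 of 16 and 13 of 22 (59.1%; Fisher's exact p = 0.49). The lists are pooled per group, so no test between replicates was possible for clusters.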

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

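All tests of the 3 patterns weighed here were chosen after the results were seen, and the counts of other splits of the samples were planned.

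HNRNPA1 transcripts of D262V SH-SY5Y cells joined the optional exon past the next exon. The change in use of the optional exon was 41.3 points in undifferentiated homozygous cells and -1.34 points in Flp-In cells, opposite ways in all libraries of both, and this difference was not tested. A sample exchanged between WT and D262V is argued against, since 0 of 15 SH-SY5Y libraries lay in the range of the other of the 2. An effect in proportion to the number of D262V alleles is argued against by heterozygous changes close to the homozygous ones. They were 93.7% of the homozygous change in use of the optional exon and 92.0% in joining past the next exon. Libraries of the 2 genotypes did not overlap in either, though, and a small effect of allele number stays open. D262V protein did not raise use of the optional exon in Flp-In cells, where it fell by 1.34 points. For joining past the next exon these cells cannot decide, since that junction was not listed there. Whether transgene reads enter the share of the optional exon is not known, so an effect of D262V protein in any cell line stays open. Also open is a change in the edited gene itself, which the homozygous and heterozygous lines may share beyond the codon, or reads shared with processed copies of HNRNPA1. DNA sequence was not analysed here.

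Gene counts lay below the reads of single junctions of the same gene. Reads set aside as ambiguous or not uniquely aligned made up at most 19.1% of an undifferentiated library. These were too few to account for counts at a median of 6.31% of a junction there. In differentiated SH-SY5Y and Flp-In libraries 0% were recorded as not uniquely aligned. Such reads may have been removed before counting, so their share cannot be judged there. Counting on the opposite strand may be the cause: in 4 of 4 comparisons the count changes followed the junction reads of the opposite-strand neighbour more closely than those of the gene itself, with r across genes of 0.26 against 0.11, 0.36 against 0.09, 0.55 against 0.41 and 0.38 against 0.23. Count levels in WT libraries followed the gene's own junction reads slightly more closely in 2 of 4 comparisons, both homozygous (rank correlation 0.192 against 0.186 in undifferentiated cells), and the neighbour's in the heterozygous (0.256 against 0.172) and Flp-In ones (0.311 against 0.248). The library kit is directional per the labels, and the strand setting is not given in the sources used here. Changes seen by junction reads as well do not rest on the counted strand alone. Junction sums come from the same libraries, though, and a shift in usage can also change them.

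Microexons were skipped more in differentiated heterozygous cells. The shared WT libraries are argued against for the part not shared with homozygous cells, because homozygous and heterozygous usage, compared directly, did not overlap at 72.2% of the 18 microexons listed in both with the same junction, with 10% by chance. An effect that grows with the number of D262V alleles is argued against by the larger change in heterozygous cells at 95.6% of the 45 microexons listed in both. Lower SRRM4 in heterozygous cells is a candidate explanation. By gene counts, the only measure tested between these genotypes, SRRM4 was higher in homozygous than in heterozygous cells by 0.98 (log2). Differences between clones other than the allele number stay open, as clones were not given separate labels.

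The D262V effect differed between differentiated and undifferentiated cells for 755 genes by the test of the interaction. Of 40 splits 1, the real one, gave as many, with 210 the highest of the others, which argues against chance there. It does not exclude chance, since 1 of 40 is the smallest share possible. Splits that mix genotypes also carry the real differences as spread, which lowers their counts. For the lists of the interaction chance cannot be excluded either, as 2 of 40 splits passed at least 6 lists, with 7 the highest. Homozygous and heterozygous cells differed in 2674 genes, with 0 the highest of the other splits. The other real and highest other counts of genes were 415 and 0 in undifferentiated homozygous, 1024 and 0 in differentiated homozygous, 2767 and 0 in heterozygous and 534 and 0 in Flp-In cells, and 7230 and 0 for differentiation. For lists they were 3 and 2, 3 and 1, 2 and 3 (2 splits as large), 1 and 7 (7 splits as large) and 4 and 3 in the same order, and 3 and 4 (2 splits as large) for homozygous against heterozygous cells. These 10 splits each are too few for a share under 0.05.

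Heterozygous SH-SY5Y and Flp-In cells moved the same way at 28.6% of the junctions listed in both. The following events moved one way in every library of one comparison and the opposite way in every library of another, differences that were not tested. A KAT2A 5' splice site changed by 15.3 points in heterozygous and -19.2 points in Flp-In cells, and one of MRPS12 by -16.9 and 15.9 points. Cassette exons of CAPN7 (16.1 and -11.7 points) and DNAH14 (-21.3 and 15.5 points) differed between the same comparisons. A RAI14 exon changed by 36.3 points in heterozygous and 29.3 points in homozygous cells, and by -13.4 points in Flp-In cells. DOCK10 had -22.6 points in undifferentiated homozygous and 35.9 points in heterozygous cells, and CMTR1 13.3 points in undifferentiated and -11.8 points in differentiated homozygous cells.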

How the results depend on the processing

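Alternatives for junction reads and for retained introns, the threshold 0.01 for the direction of cassette exons and the libraries left out for directions were chosen after the data were seen, and the others were planned. No called result reversed its direction under any alternative run, but the balance of higher and lower genes did under at least 1 alternative in 6 comparisons, all but differentiation. In the interaction 354 positive and 401 negative became 876 and 796 with DESeq2 and 435 and 351 with RLE. Homozygous against heterozygous cells went from 1440 higher and 1234 lower to 1311 and 1404 with DESeq2 and 1295 and 1351 with RLE. Up and down numbers went from 525 and 499 to 497 and 509 with RLE in differentiated homozygous cells, and to 858 and 974 in the fit of their 6 libraries alone. With RLE they went from 1342 and 1425 to 1388 and 1315 in heterozygous cells. They went from 176 and 239 to 203 and 184 without WT library 1 in undifferentiated homozygous cells. In Flp-In cells 252 and 282 became 263 and 241 with no filter, 240 and 218 without D262V library 1, and 146 and 121 without library 3. DESeq2 kept more down than up in Flp-In cells, with 162 up and 275 down. The difference in irCLIP clusters between included and skipped exons of undifferentiated cells, not called, went from 6.35 to -3.54 points within 300 nt of a splice site. Of the values under alternatives 109 stayed on the same side of the threshold or within 1.5 times, 24 were weaker, 10 stronger and 9 moved. All 280 calls of named genes kept their direction, and 79 lost the call under at least 1 alternative: 19 of 23 in undifferentiated homozygous, 11 of 45 in differentiated homozygous, 17 of 74 in heterozygous and 21 of 26 in Flp-In cells (13 with DESeq2), 3 of 10 for the interaction, 8 of 92 for differentiation and 0 of 10 for homozygous against heterozygous cells. Of simulated 2-fold changes 22% were recovered in undifferentiated, 43% in Flp-In and 79% in differentiated cells, the last with the gene number of the 6-library fit. Whether depth set this was not tested. Where a value changed, the cause was not tested unless one is named.

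Genes changed in undifferentiated homozygous cells numbered 817 with DESeq2, whose simulated false calls were 24.8% there, and 816 with no filter, each including 414 of the 415. Differentiated homozygous cells had 1832 in a fit of the 6 libraries alone (1011 shared). The interaction had 1672 with DESeq2 (755 shared) and 1184 with no filter (705 shared). Without 1 library the counts were 98 to 428 in undifferentiated homozygous, 575 to 783 in differentiated homozygous, 1971 to 2825 in heterozygous and 209 to 714 in Flp-In cells, 1772 to 3041 for homozygous against heterozygous cells, 359 to 1189 for the interaction and 5799 to 7805 for differentiation. Fewer libraries lower the power of a test, yet some counts rose. The undifferentiated count was 201 without WT library 2, and 105, 164 and 98 without homozygous libraries 1, 2 and 3. The differentiated homozygous count was 575 and 609 without WT libraries 1 and 2, and 653, 650 and 675 without homozygous libraries 1, 2 and 3. Homozygous against heterozygous cells gave 1772 without homozygous library 1. Flp-In cells gave 277, 265 and 209 without WT libraries 1, 2 and 3 and 267 without D262V library 3. The interaction gave 1173 and 1189 without undifferentiated WT libraries 1 and 3, 424, 359 and 462 without differentiated WT libraries 1, 2 and 3, and 382, 400 and 427 without differentiated homozygous libraries 1, 2 and 3. By junction reads the ranges were 304 to 654, 1243 to 2020, 919 to 2049 and 385 to 551 in undifferentiated homozygous, differentiated homozygous, heterozygous and Flp-In cells. The first was 352 without WT library 2 and 324, 304 and 306 without homozygous libraries 1, 2 and 3, and the heterozygous one 919 and 982 without WT libraries 1 and 2.

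With the replicate block 237 genes changed in undifferentiated homozygous cells, 234 of them shared. Residuals of libraries with the same replicate number correlated at -0.052 to 0.029 in differentiated, -0.0050 to 0.034 in undifferentiated and 0.015 to 0.050 in Flp-In cells, and those with different numbers at -0.029 to 0.052, -0.040 to 0.030 and -0.053 to 0.028. In Flp-In cells all 3 pairs with the same number were positive, so a weak pairing there is not excluded.

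With an estimated correlation 0 lists passed by gene counts in each D262V comparison, in homozygous against heterozygous cells and in the interaction, and 2 for differentiation. With fry, which asks only whether a list's own genes moved, 4 passed in each of undifferentiated homozygous, differentiated homozygous and heterozygous cells. It passed 10 for homozygous against heterozygous cells, 5 for the interaction, 21 for differentiation and 0 in Flp-In cells.

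Changed splicing events in undifferentiated homozygous, differentiated homozygous, heterozygous and Flp-In cells numbered 86, 96, 305 and 32 with a change of at least 0.2, and 84, 89, 306 and 17 with the authors' adjusted p under 0.01, stricter settings by construction. With at least 50 reads they were 127 in undifferentiated and 49 in Flp-In cells. Without 1 library they were 195 to 227, 175 to 184, 575 to 594 and 70 to 80. The share of cassette exons skipped more in heterozygous cells was 65.9% with a change of at least 0.2 (adjusted p = 0.022), 69.4% with p under 0.01 (adjusted p = 2.2e-04) and 58.9% to 62.1% without 1 library, passing at 59.8% without heterozygous library 2, 61.9% without heterozygous library 3, 62.1% without WT library 2 and 60.2% without WT library 3. The share of introns retained less in undifferentiated cells was 20.0%, 22.2% and 23.8% with a change of at least 0.2, p under 0.01 and at least 50 reads, no longer passing with fewer events. In Flp-In cells that share was 0% to 12.5% without 1 library, passing at 0% without D262V library 1 or WT library 1 and at 10.0% without D262V library 3. Undifferentiated and differentiated homozygous cells moved the same way at 66.7% of junctions changed by at least 0.1 in both (exact binomial adjusted p = 0.25). At cassette exons the share was 63.6% (adjusted p = 0.055). Both differentiated genotypes moved the same way at 97.0% of junctions changed by at least 0.1 in both, where simulated shared controls alone gave 95.7%. With a reciprocal overlap, 69.6% and 74.1% of WT and D262V clusters were shared in Flp-In and 70.8% and 75.8% in SH-SY5Y cells, and among the higher-scored part of each list 84.1%, 88.4%, 85.4% and 90.5%.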

Other observations

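The tests reported here were planned, apart from those by junction reads and by opposite-strand partners.

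Several fixed lists showed single genes rather than a shared direction by camera. Synaptic genes in differentiated homozygous cells had SYT4, a synaptotagmin, up (0.80, SE 0.17, and 0.71 by junction reads) and none down of 36. The list adjusted p was 0.616, with 3 up adjusted over the list alone. With fry, however, this list was higher in homozygous cells (adjusted p = 0.0497). In heterozygous cells 2 synaptic genes rose, with GRIA3, a glutamate receptor subunit, at 1.54 (junction reads 1.09). There 3 fell, including the vesicle protein gene SYP (-0.61), with list adjusted p = 0.641. Voltage-gated channel genes had 2 of 18 up and 1 down in homozygous cells (list adjusted p = 0.83), with CACNA1C at 0.90 (SE 0.27; junction reads 0.87). The noradrenergic identity list had 2 of 19 up and 3 down in both genotypes (list adjusted p = 0.853 and 0.6). Adjusted over the list alone, 5 were up and 3 down in homozygous cells. GATA3 rose in heterozygous cells by 1.06 (junction reads 1.09). Of 20 stress granule components 1 rose and none fell in homozygous cells, and 2 rose and 3 fell in heterozygous cells (list adjusted p = 0.668 and 0.6), and PABPC1, the poly(A)-binding protein gene, rose by both measures in both (0.85, SE 0.19, and 0.88, SE 0.19). PMP22, of the 9 Schwann and glial markers (1 up in homozygous and 2 up in heterozygous cells, none down), rose in both (1.68, SE 0.25, and 1.33, SE 0.26; list adjusted p = 0.997 and 0.552).

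In heterozygous cells the vascular growth factor gene VEGFA rose (1.58, SE 0.30; junction reads 1.37) while the hexokinase gene HK2 fell (-0.89) in the hypoxia and glycolysis list of 17 (list adjusted p = 0.6). IFIT3 rose (1.34, SE 0.18), the 1 of 6 interferon response genes to pass (adjusted p = 0.81), and MTHFD2, a mitochondrial folate enzyme gene, rose (0.78), the 1 of 18 genes of the unfolded protein and integrated stress response (adjusted p = 0.81). Of 14 p53 targets 2 rose (adjusted p = 0.81), of 18 proliferation genes 1 rose and 2 fell (adjusted p = 0.81), and of 10 heat shock genes 2 fell, HSPB1 (-0.77) and DNAJA1 (-0.49; adjusted p = 0.552). Activity-regulated genes had 1 of 13 up and 4 down (adjusted p = 0.673), with EGR3 at -3.11 and DUSP6 at 0.86. None of 14 genes of nonsense-mediated decay and none of 15 genes with known hnRNPA1-regulated splicing passed by gene counts with edgeR in heterozygous cells (adjusted p = 0.971 for both lists). In homozygous cells SMG6 fell (-0.61) in the first of these lists and none passed in the second (adjusted p = 0.997 and 0.709).

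The mitochondrial gene MT-ND6, coded on the other strand from most mitochondrial genes, had 44568 reads against 10244 for MT-ND5 in WT Flp-In cells, 234703 against 101493 in undifferentiated and 91330 against 121118 in differentiated WT SH-SY5Y cells. Some genes called by gene counts had no listed junctions of their own but an opposite-strand partner with junction reads. They moved in the direction of the partner's reads in 8 of 8 cases in undifferentiated homozygous and 7 of 7 in differentiated homozygous cells. In heterozygous cells 18 of 19 did, and in Flp-In cells 7 of 7.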
